A study of Rattus norvegicus with 24 samples.

How the data were processed

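The samples were total RNA of rat kidney on 24 cDNA arrays with 2 channels, with Cy5 in channel 1 and Cy3 in channel 2. The deposited table holds 1 log ratio per probe and array, and its log base, its numerator and the authors' steps before it are not given in the sources used here. It has 3742 probe identifiers, of which 1766 had a value on at least 1 array and 701 on all 24. The deposited log ratios of each array were centred on the mean (largest absolute mean 0.00082) and not on the median (largest absolute median 0.067). No pair of arrays shared values exactly (0 values). Array titles gave the strain, the time and both rats of each array. An array pairs a rat numbered 1 to 3 with a rat of a higher number, and the replicate is the number of the lower one.

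Gene symbols came from the annotation of the array. Of the measured probes 1426 had 1 symbol, 29 had several and 311 had none, and 1421 of the 1426 were found in the rat gene table by gene number, while 5 kept the symbol of the annotation. Probes without a single symbol were tested and counted but not named. Chromosome positions were not used.

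Each array was centred on its median, and the arrays of both dye orientations of a pair were averaged into 1 value per pair. The design set before the data were examined would have turned 1 array of each pair, on the assumption that ratios were Cy5 over Cy3. The values contradicted that assumption and the arrays were not turned. With the mean of other arrays of the same orientation removed, swapped arrays of a pair correlated positively in 12 of 12 pairs (r from 0.301 to 0.894, against a mean of -0.0483 for opposite arrays of different pairs). Differences between swapped arrays, which hold the dye effect, were alike in all pairs (r from 0.511 to 0.793, with 74.4 percent of their variance on 1 component), and means of swapped arrays were less so (r from -0.0862 to 0.76, 47.2 percent). Turning by dye was kept as an alternative.

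The model was limma with 1 coefficient per group over all 12 pairs (8 residual degrees of freedom with all pairs), moderated by eBayes, with two-sided tests and Benjamini-Hochberg adjustment over probes at 0.05. A probe was tested where at least 2 of 3 pairs of each group in the comparison had both orientations. Comparisons were each group against 0, SS minus SS-13BN/Mcw at each time, both strain contrasts together by an F test, 3 days minus overnight in each strain, and the mean of the 4 groups. The p-values measure the spread between rat pairs. Deviations from the group mean were more alike between times for the same low rat number than for different numbers (mean r 0.363 against -0.183 in SS and 0.323 against -0.156 in SS-13BN/Mcw), though rat 2 of SS stood at -0.024. Deviations of the 3 pairs of a group sum to 0. This ties the mean r for different numbers to that for the same number, so it is no separate evidence. The titles repeat the low rat numbers at both times, so pairs of a strain were taken to be linked. The main fit does not use that link, and a fit with that rat as a block was run beside each comparison. Software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with matplotlib 3.10.9 for figures.

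For the gene lists, 23 lists of kidney pathways and cell type markers were written before the data were examined, and so were the comparisons, the thresholds, the alternatives and the rule for named genes. Lists with at least 5 measured genes were tested by cameraPR of limma on the moderated statistics, with probes of a gene averaged and a preset correlation of 0.01, adjusted over lists within a comparison. Beside it camera with an estimated correlation and fry were run on genes with a value in all 12 pairs. With the estimated correlation 0 lists passed in any comparison. By fry, which asks whether a list moves on balance one way, the numbers were 2 and 5 in SS-13BN/Mcw overnight and at 3 days, 2 for the strain difference at 3 days, 1 for the time difference in SS-13BN/Mcw, 5 for the common response and 0 elsewhere.

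Named genes were, for each group, up to 8 per direction with the largest change among those past the threshold with the same sign in every measured pair. Where fewer passed, the next by smallest p with 1 sign in every pair filled up to 5 per direction and are given as not past the threshold. For differences and the common response up to 5 per direction followed the same rule, for the F test 5 in all, and for each list past its test the 4 members with the smallest p. For a difference the rule asked that the pair values of both groups did not overlap. List members were named whatever their signs, and some are given without their own p where they did not pass.

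Each fit was tested on simulated data with the missing values of the real table, where 100 probes had a change of 0.5 and 100 a change of 1 in log-ratio units. Changes of 0.5 were recovered in 81 percent of probes for SS overnight, 93 for SS at 3 days, 78 and 83 for SS-13BN/Mcw overnight and at 3 days, 63 and 66 for the strain differences overnight and at 3 days, 66 for each time difference, 99 for the common response and 61 for the F test. Changes of 1 were recovered in 90 to 100 percent, and 1.86 to 6.83 percent of calls were false. Lists of 12 genes with each moderated statistic shifted by 2 were called in 100 percent of cases and unshifted ones in 1.5 to 6.5 percent. These calls were at an unadjusted p under 0.05, and the shift was not matched to the real lists. Genes and pairs were simulated as independent of each other, so these rates need not hold for lists of correlated genes. The estimated correlation was 0.708 for proximal tubule markers, 0.447 for ribosomal protein genes and 0.219 for matrix genes.

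Alternatives were values as deposited, arrays scaled to one median absolute deviation, quantile normalization, all 3 pairs required, single orientations also used, pairs with a gap above 1 between orientations left out, an array-level fit with a dye term, robust eBayes, a fit of the groups compared alone, the low-numbered rat as a block, a threshold of 0.1 and each pair left out in turn. The gap of 1 was planned on the log2 scale and applied in the deposited units. Turning by dye, for counts, named genes, lists and correlations, and leaving out pairs in the correlations, were chosen after seeing the data. Correlations between groups were set against 100 simulations in which no probe responded and the low-numbered rats were shared.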

Results

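Kidney gene expression was compared between rats on low and high salt in 2 strains, the Dahl salt-sensitive SS rat and SS-13BN/Mcw, a consomic strain that carries chromosome 13 of the Brown Norway rat on the SS background. Each of 24 arrays compared the total RNA of a low-salt and a high-salt rat of the same strain in Cy5 and Cy3. The arrays fell into 4 groups of 3 rat pairs, SS and SS-13BN/Mcw overnight and at 3 days after the change of salt, and each pair was hybridised in both dye orientations. An array held a value for 877 to 1412 probes, 1766 probes had a value on at least 1 array, and the number of arrays limits the precision.

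All values are log ratios in the units of the deposited table, whose log base is not stated, so no folds are given. A value of 1 would be a fold of 2 in base 2 and of 10 in base 10. The table does not state which rat is the numerator. Genes are therefore described as lying on the positive or the negative side of the ratio, and no direction with salt is given. The ratio was taken to run the same way in all 4 groups. It was also taken to be turned to one rat-to-rat direction already. Both arrays of a pair gave like values once the part shared by all arrays of a dye orientation was removed (r from 0.301 to 0.894 in 12 of 12 pairs). Before that removal their r ran from -0.0595 to 0.749 and was below 0 in some pairs. The array titles give rats 1 to 3 of a strain to the pairs of both times, so the overnight and 3-day groups of a strain are likely linked. The main fit nevertheless treats all 12 pairs as independent, and a fit with the low-numbered rat as a block stands beside it. The slides of each SS group were numbered apart from those of all other groups, so slide order and group cannot be told apart in the strain comparisons and in the time comparison of SS. The slides of both SS-13BN/Mcw groups overlapped in order. Genes named for the size of their change had the same sign in each of their measured pairs. Values of single groups are means ± SD over rat pairs. For differences between groups and for the common response, ± gives the standard error (SE) of the fitted value throughout. Adjusted p is from limma, and lists of genes were tested against all other genes.

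The overnight response of SS rats, which asks what changed in the salt-sensitive strain within the shortest time, had more probes past the threshold on the positive than on the negative side. Timp1, an inhibitor of matrix metalloproteinases, stood at 0.76 ± 0.17 (n = 3, adjusted p = 0.0109), and Serpinh1, a chaperone of collagen in the endoplasmic reticulum, at 0.55 ± 0.18 (n = 3, adjusted p = 0.0208). Col3a1, a fibrillar collagen chain, stood at 0.71 ± 0.45 (n = 3, adjusted p = 0.0435). In all, 13 of 1139 probes passed, 11 positive and 2 negative, and 174 had an unadjusted p under 0.05 where 56.95 would by chance.

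Among the other positive genes were Serpina3n, a secreted protease inhibitor, at 0.65 ± 0.22 (adjusted p = 0.0249), Mt2A, a metal-binding metallothionein, at 0.57 ± 0.10 (adjusted p = 0.0177), and Vcam1, an adhesion molecule for leukocytes, at 0.59 ± 0.18 (adjusted p = 0.0316). Csnk2b, a regulatory subunit of a casein kinase, reached 0.80 ± 0.42 (adjusted p = 0.0305) and Tsc22d1, a transcriptional regulator, 0.70 ± 0.33 (adjusted p = 0.0208). The 2 negative genes were the kinase Akt1 at -0.73 ± 0.095 in 2 pairs (adjusted p = 0.0369) and Hpd, an enzyme of tyrosine breakdown, at -0.49 ± 0.14 in 3 pairs (adjusted p = 0.0305). Kap, an androgen-regulated protein of the proximal tubule, at -0.98 ± 0.69 (adjusted p = 0.0688), the epoxide hydrolase Ephx1 at -0.34 ± 0.20 (adjusted p = 0.0658) and the transcription factor Foxq1 at -0.52 ± 0.29 (adjusted p = 0.0688) did not pass.

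Of 19 gene lists tested in SS overnight, 6 passed. Extracellular matrix genes averaged 0.27, with 16 of 19 on the positive side and 3 past the threshold, 6 when adjusted over the list alone (list adjusted p = 4.48e-05; adjusted p = 0.484 with an estimated correlation). Proximal tubule markers averaged -0.463, with 11 of 12 negative and 0 past the threshold, 4 when adjusted over the list alone (list adjusted p = 7.52e-05; adjusted p = 0.484 with an estimated correlation). Beside Kap these held Hao2, a peroxisomal oxidase, at -0.79 ± 0.29, Anpep, a brush border aminopeptidase, at -0.90 ± 0.51, and the epoxygenase Cyp2c23 at -0.60 ± 0.18. All 6 thick ascending limb and distal tubule markers were negative, among them Slc12a1, the sodium-potassium-chloride cotransporter, at -0.28 ± 0.11, and Ppp1r1a, a phosphatase inhibitor, at -0.32 ± 0.17. Their mean was -0.185, with 0 past the threshold and 2 when adjusted over the list alone (list adjusted p = 0.00915; adjusted p = 0.257 with an estimated correlation).

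Cytosolic ribosomal proteins averaged 0.11 in SS overnight, with 28 of 29 positive and 0 past the threshold, also 0 when adjusted over the list alone (list adjusted p = 0.00537; adjusted p = 0.577 with an estimated correlation). Rpl39 stood at 0.24 ± 0.23 and Rps6 at 0.19 ± 0.24, each positive in 2 of 3 pairs. Inflammation and adhesion genes averaged 0.227, with 8 of 9 positive and Vcam1 alone past the threshold, also 1 when adjusted over the list alone (list adjusted p = 0.00537). The interleukin receptor Il6r stood at 0.23 ± 0.13, the transcription factor Irf1 at 0.31 ± 0.28 and the complement gene C1qb at 0.33 ± 0.47, the latter positive in 2 of 3 pairs. Genes of arachidonic acid metabolism averaged -0.24, with 5 of 6 negative and 0 past the threshold, but 4 negative and 1 positive when adjusted over the list alone (list adjusted p = 0.0199). The positive one was Alox5ap, which takes part in leukotriene synthesis, at 0.24 ± 0.0565, and the prostaglandin receptor Ptger1 stood at -0.34 ± 0.21. For both of these lists too few genes had a value in all 12 pairs to estimate a correlation.

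The balance of the 13 probes in SS overnight depended on the processing. It was 30 positive and 21 negative with arrays scaled to one spread, 31 and 34 after quantile normalization, 34 and 15 of 49 in an array-level fit, and 14 and 17 of 31 in a fit of this group alone. Without pair 1 or without pair 3 of this group 0 probes passed in limma, with 77 and 213 at an unadjusted p under 0.05, and without pair 2 there were 6.

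In SS rats at 3 days few probes passed, and these were positive. Serpina3n stood at 0.88 ± 0.13 (n = 2, adjusted p = 0.032), Serpinh1 at 0.60 ± 0.24 (n = 3, adjusted p = 0.032) and Tubb5, a tubulin, at 0.45 ± 0.13 (n = 3, adjusted p = 0.0431). These 3 were the probes that passed of 883 tested, and 108 had an unadjusted p under 0.05 where 44.15 would by chance. The collagen chain Col1a1 had a larger mean of 1.10 ± 0.58 in 3 of 3 pairs, which did not pass (adjusted p = 0.065).

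Further genes with the smallest p in SS at 3 days did not pass. They were the chaperone calreticulin (Calr) at 0.32 ± 0.037 and the cell polarity gene Pard3 at -0.73 ± 0.33 (both adjusted p = 0.065). Also among them were Ephx1 at -0.32 ± 0.075 and the proprotein convertase Pcsk6 at -0.26 ± 0.095 (both adjusted p = 0.13), and the glucagon receptor Gcgr at -0.42 ± 0.26 and Ppp1r1a at -0.31 ± 0.086 (both adjusted p = 0.158). Of 18 lists 3 passed. Extracellular matrix genes averaged 0.278, 11 of 15 positive, with 1 past the threshold and 5 when adjusted over the list alone (list adjusted p = 3.04e-05; adjusted p = 0.4 with an estimated correlation). The basement membrane gene Nid1 stood at 0.40 ± 0.25. Proximal tubule markers averaged -0.468, 9 of 9 negative, with 0 past the threshold and 5 when adjusted over the list alone (list adjusted p = 2.21e-05; adjusted p = 0.4 with an estimated correlation). The brush border peptidase Dpp4 stood at -0.38 ± 0.21. Thick ascending limb and distal tubule markers averaged -0.168, 6 of 6 negative, with 0 past the threshold and 3 when adjusted over the list alone (list adjusted p = 0.00687; adjusted p = 0.391 with an estimated correlation). The growth factor Egf stood at -0.25 ± 0.18. In each of these 3 lists pair 1 lay farthest from 0. Mean scores of pairs 1, 2 and 3 were 0.528, 0.261 and 0.0451 for matrix genes. They were -0.94, -0.27 and -0.18 for proximal tubule markers, and -0.324, -0.144 and -0.0352 for thick ascending limb and distal tubule markers. With the low-numbered rat as a block 5 probes passed, with arrays scaled to one spread 9 (7 positive, 2 negative), after quantile normalization 16 (9 and 7), in an array-level fit 38, and with all 3 pairs required 1. In limma 0 passed in a fit of this group alone and without its pair 1 or pair 2 (65, 50 and 83 at an unadjusted p under 0.05), and 10 without pair 3.

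In the fit over all groups SS-13BN/Mcw rats overnight had more probes past the threshold than the other 3 groups, but fitted alone they had 0, against 31 in SS overnight and 30 in SS-13BN/Mcw at 3 days. Genes of the proximal tubule lay far on the negative side. Anpep stood at -1.84 ± 0.76 (n = 3, adjusted p = 0.00665), Acsm2, a medium-chain acyl-CoA ligase, at -1.76 ± 0.85 (n = 3, adjusted p = 0.00984) and Aadat, an aminotransferase of lysine and kynurenine metabolism, at -1.70 ± 0.76 (n = 3, adjusted p = 0.00627). On the positive side were Serpina3n at 0.74 ± 0.31 (n = 3, adjusted p = 0.00627) and Timp1 at 0.71 ± 0.23 (n = 3, adjusted p = 0.00627). Of 1100 probes 116 passed, 35 positive and 81 negative, and 106 of them had a gene name.

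The other negative genes named were Hao2 at -1.58 ± 0.89 and the glutathione transferase Gsta2 at -1.55 ± 0.85 (both adjusted p = 0.00627). They also included the mitochondrial aminotransferase Agxt2 at -1.39 ± 0.61 and the endocytic receptor megalin (Lrp2) at -1.33 ± 0.69 (both adjusted p = 0.01). The brush border enzyme Ggt1 stood at -1.35 ± 0.71 (adjusted p = 0.0107). Positive genes were Serpinh1 at 0.54 ± 0.15 (adjusted p = 0.00967), P4ha1, a hydroxylase of collagen prolines, at 0.66 ± 0.27 (adjusted p = 0.0419), and clusterin (Clu), a secreted chaperone, at 0.56 ± 0.14 (adjusted p = 0.01). They also included the cytoskeletal genes Pdlim1 at 0.60 ± 0.25 (adjusted p = 0.01) and Dynll1 at 0.59 ± 0.15 (adjusted p = 0.00627), and Tsc22d1 at 0.57 ± 0.23 (adjusted p = 0.0167).

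Of 19 lists 3 passed in SS-13BN/Mcw overnight. Proximal tubule markers averaged -0.848, with 13 of 14 negative, 10 past the threshold and 12 when adjusted over the list alone (list adjusted p = 3.67e-10; adjusted p = 0.421 with an estimated correlation). They included Dpp4 at -0.73 ± 0.32 (adjusted p = 0.00627) and the peptide transporter Slc15a2 at -0.89 ± 0.47 (adjusted p = 0.00665). Extracellular matrix genes averaged 0.318, 17 of 19 positive, with 3 past the threshold and 5 when adjusted over the list alone (list adjusted p = 0.000138; adjusted p = 0.659 with an estimated correlation). The gelatinase Mmp2 stood at 0.46 ± 0.27 in 2 pairs (adjusted p = 0.0465). Ribosomal protein genes averaged 0.101, 24 of 29 positive, with 0 past the threshold and 0 when adjusted over the list alone (list adjusted p = 0.0453; adjusted p = 0.659 with an estimated correlation). Among them were Rpl31 at 0.26 ± 0.039 and the initiation factor Eif5 at 0.25 ± 0.20. By fry proximal tubule markers passed (adjusted p = 0.00996), and matrix (0.0833) and ribosomal protein genes (0.172) did not. The count of 116 fell to 12 without pair 3 and to 45 without pair 2 of the group, against 92 without pair 1. An array-level fit gave 226, and a fit of this group alone gave 0 in limma with 280 at an unadjusted p under 0.05.

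At 3 days SS-13BN/Mcw rats had proximal tubule genes far on the negative side, while the 17 matrix genes averaged -0.00771 (list adjusted p = 0.897). Kap stood at -1.71 ± 0.23 (n = 3, adjusted p = 0.00853) and Anpep at -1.62 ± 0.40 (n = 3, adjusted p = 0.0206). Hsd11b1, the enzyme that regenerates active glucocorticoid, stood at -1.10 ± 0.14 (n = 3, adjusted p = 0.00853), against -0.16 ± 0.22 overnight (difference -0.94 ± 0.23, SE, adjusted p = 0.276). Scnn1a, a subunit of the epithelial sodium channel, at 0.28 ± 0.088 (n = 3, adjusted p = 0.0293) and Atp1b1, a subunit of the sodium pump, at 0.41 ± 0.22 (n = 3, adjusted p = 0.0351) were positive. In all 27 of 907 probes passed, 6 positive and 21 negative, 25 of them with a gene name.

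Further negative genes were Gsta2 at -1.48 ± 0.19, Aadat at -1.47 ± 0.043 and the aldehyde reductase Akr7a3 at -1.22 ± 0.31 (each adjusted p = 0.0146). Others were Hao2 at -1.35 ± 0.18 (adjusted p = 0.0202) and Acsm2 at -1.44 ± 0.41 (adjusted p = 0.0351). The other positive genes were the growth factor Pdgfa at 0.44 ± 0.29 (adjusted p = 0.0273) and the acyl-CoA synthetase Acsl3 at 0.43 ± 0.24 (adjusted p = 0.0293). They also included the receptor gene Gnrhr at 0.41 ± 0.21 (adjusted p = 0.0428) and the ubiquitin ligase component Rbck1 at 0.34 ± 0.081 (adjusted p = 0.0146). Proximal tubule markers were the 1 list of 17 that passed, with a mean of -0.791, 10 of 12 negative, 6 past the threshold and 10 when adjusted over the list alone (list adjusted p = 9.59e-11; adjusted p = 0.414 with an estimated correlation). Slc15a2 stood at -0.93 ± 0.20 (adjusted p = 0.0146) and Dpp4 at -0.60 ± 0.18 (adjusted p = 0.0202). By fry proximal tubule markers passed too (adjusted p = 0.0184). Without pair 2 or without pair 3 of the group 0 probes passed in limma, and without pair 1 there were 29. With arrays scaled to one spread 61 passed, after quantile normalization 64 and in an array-level fit 58.

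**Figure D1:**
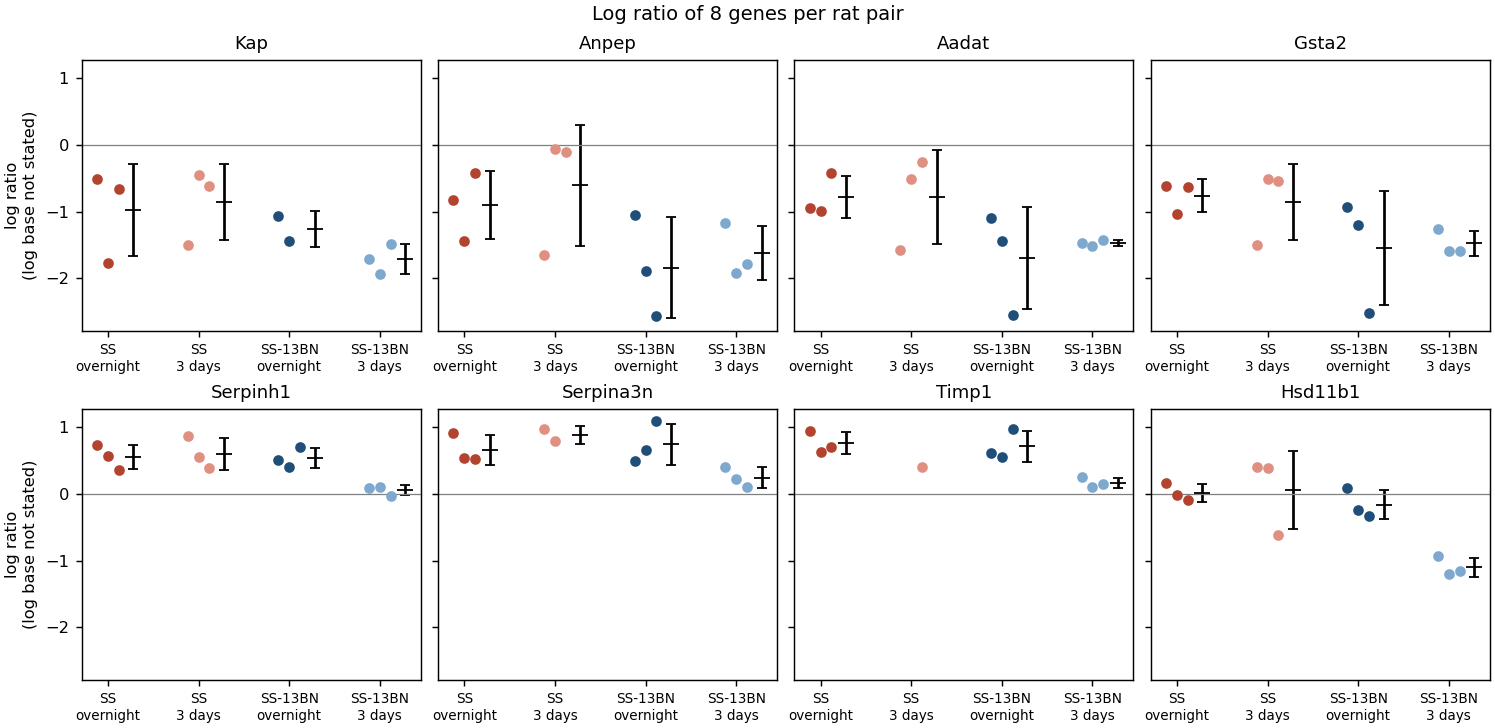
Log ratio (base not stated) of 8 genes on the vertical axis in each rat pair (points) of the 4 groups, with the mean and SD of a group as black bars. Kap, Anpep, Aadat and Gsta2 lie below 0 in every measured pair, and Hsd11b1 has a mean of -1.10 in SS-13BN/Mcw at 3 days and of 0.06 in SS at that time. The SS pairs of Hsd11b1 at 3 days run from -0.62 to 0.40.

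The common response, the mean of the 4 groups, asks what differed from 0 on average over both strains and both times, and a gene can pass without a like value in each group. Of 822 probes 234 passed, 110 positive and 124 negative, in the main fit, which treats the pairs as independent. With the low-numbered rat as a block, which allows for rats shared by both times, 176 passed, 80 positive and 96 negative. The majority was positive with values as deposited (137 and 110), in an array-level fit (147 and 140), without pair 3 of SS overnight (135 and 134) and without pair 3 of SS at 3 days (138 and 124). Among positive genes with 1 sign in every measured pair were Serpina3n at 0.63 ± 0.0614 (SE, adjusted p = 0.00013) and Mt2A at 0.39 ± 0.045 (SE, adjusted p = 0.000149). On the negative side were Anpep at -1.24 ± 0.161 (SE, adjusted p = 0.00029), Kap at -1.20 ± 0.125, Aadat at -1.18 ± 0.13 and Gsta2 at -1.16 ± 0.128 (SE, each adjusted p = 0.00013). Acsm2 stood at -1.15 ± 0.163 (SE, adjusted p = 0.00057).

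Other positive genes of the common response were the actin-binding peptide gene Tmsb10 at 0.34 (adjusted p = 0.00029), Actb, which encodes beta-actin, at 0.30 (adjusted p = 0.000336) and Atp1b1 at 0.28 (adjusted p = 0.00124). Of 17 lists 4 passed. All 9 proximal tubule markers were negative with a mean of -0.748, 8 past the threshold and 8 when adjusted over the list alone (list adjusted p = 2.09e-12; adjusted p = 0.29 with an estimated correlation). Hao2 stood at -1.11 (adjusted p = 0.000149), Slc15a2 at -0.60 (adjusted p = 0.00029) and Dpp4 at -0.48 (adjusted p = 0.000149), negative in 12 of 12 pairs. All 6 thick ascending limb and distal tubule markers were negative with a mean of -0.144, 2 past the threshold and 4 when adjusted over the list alone (list adjusted p = 0.0307; adjusted p = 0.29 with an estimated correlation). Slc12a1 stood at -0.24 (adjusted p = 0.00124) and Ppp1r1a at -0.21 (adjusted p = 0.00295), each negative in 11 of 12 pairs. By fry both of these marker lists passed (adjusted p = 0.00137 each).

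Extracellular matrix genes averaged 0.209 over the 4 groups, with 12 of 15 positive, 9 positive and 1 negative past the threshold and the same numbers when adjusted over the list alone (list adjusted p = 0.00332; adjusted p = 0.583 with an estimated correlation). Serpinh1 stood at 0.43 (adjusted p = 0.00013), Col1a1 at 0.69 (adjusted p = 0.00118), Col3a1 at 0.38 (adjusted p = 0.00535) and the proteoglycan Bgn at 0.32 (adjusted p = 0.01), positive in 11 of 12 pairs except Col3a1, which was in 9 of 11. Ribosomal protein genes averaged 0.074, 24 of 27 positive, with 5 past the threshold and 4 when adjusted over the list alone (list adjusted p = 0.0302; adjusted p = 0.778 with an estimated correlation). Among them were Rpl39 and Rpl31 at 0.18, Rpl41 at 0.17 and Rps13 at 0.16 (adjusted p from 0.0123 to 0.0297), each positive in 9 or 10 of 12 pairs. By fry matrix genes passed (adjusted p = 0.0118) and ribosomal protein genes did not (0.0714).

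**Figure D2:**
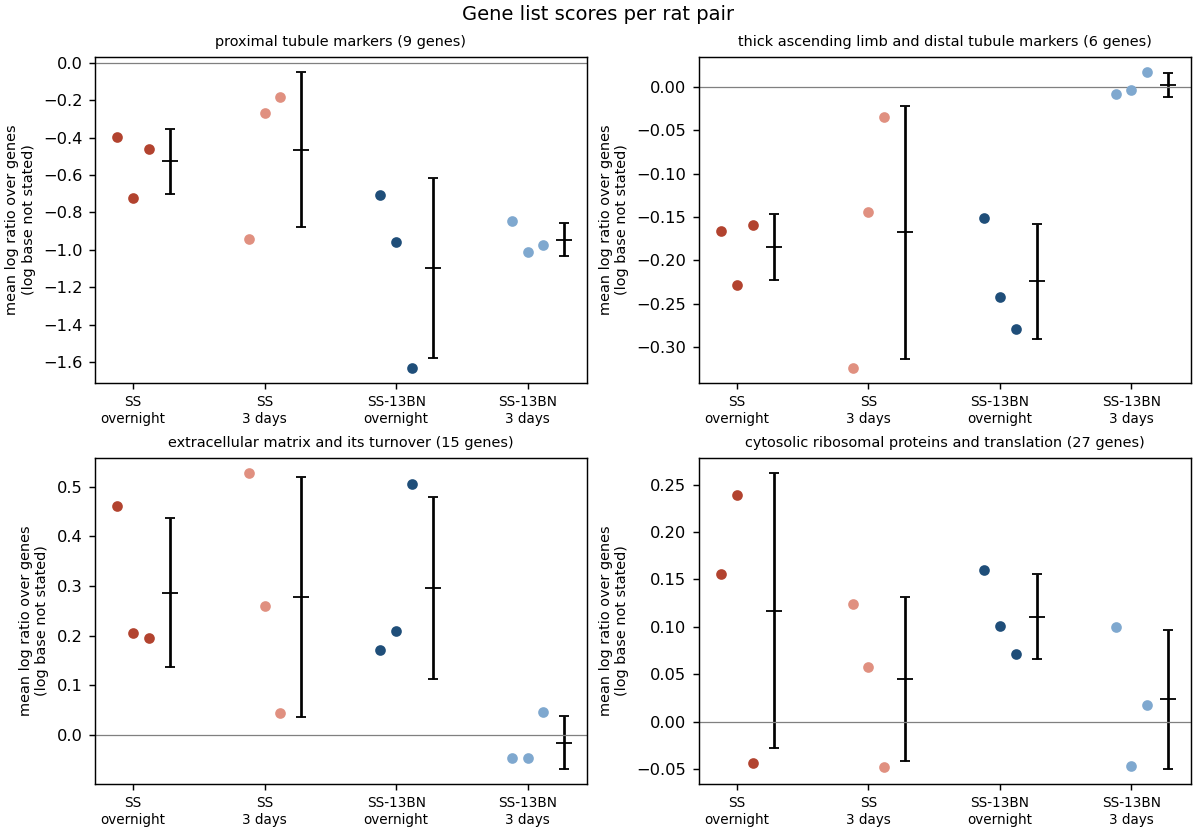
Mean log ratio (base not stated) over the genes of 4 lists on the vertical axis in each rat pair (points) of the 4 groups, with the mean and SD of a group as black bars; vertical scales differ between panels. The proximal tubule score is below 0 in 12 of 12 pairs, from -1.63 to -0.18, and 2 of 12 pairs have a matrix score below 0.

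The strain comparisons ask whether SS and SS-13BN/Mcw differed in their response, and their differences are SS minus SS-13BN/Mcw. Overnight, proximal tubule markers lay less far on the negative side in SS, with a mean difference of 0.44 and 10 of 12 genes positive (list adjusted p = 0.000187; adjusted p = 0.62 with an estimated correlation). Slc15a2 differed by 0.68 ± 0.216 (SE), Dpp4 by 0.50 ± 0.161, Lrp2 by 0.76 ± 0.336 and the peptidase Mme by 0.45 ± 0.184. Antioxidant and oxidant enzymes differed by 0.201 on average, 17 of 20 positive (list adjusted p = 0.00451; adjusted p = 0.713 with an estimated correlation). Gsta2 differed by 0.79 ± 0.361, glutathione synthetase (Gss) by 0.48 ± 0.188, Gclm, of glutathione synthesis, by 0.44 ± 0.233 and the peroxidase Gpx4 by 0.34 ± 0.144. No single gene of either list passed, over all genes or when adjusted over the list alone. Lists numbered 2 of 19 past the threshold, but 0 without pair 3 of SS-13BN/Mcw overnight (smallest adjusted p = 0.0512).

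Of 1053 probes 0 passed for the strain difference overnight in limma, 53 had an unadjusted p under 0.05 where 52.65 would by chance, and an array-level fit gave 1. The genes with the smallest p had an adjusted p of 0.898. On the positive side they were the anticoagulant protein S gene Pros1 at 0.43 ± 0.116, cytochrome c (Cycs) at 0.66 ± 0.204, the myosin light chain Myl2 at 0.46 ± 0.13, the acyl-CoA dehydrogenase Acads at 0.58 ± 0.18, and Slc15a2. On the negative side they were Foxq1 at -0.71 ± 0.175, the anchoring protein gene Akap9 at -0.29 ± 0.107, the secreted Wnt modulator Sfrp4 at -0.39 ± 0.155, the G protein subunit Gng7 at -0.20 ± 0.0908, and the stress-response gene Ppp1r15a at -0.49 ± 0.214.

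At 3 days, matrix genes were higher in the ratio in SS than in SS-13BN/Mcw, by 0.295 on average with 11 of 15 positive (list adjusted p = 0.00446; adjusted p = 0.416 with an estimated correlation). With 0 past the threshold, 3 passed when adjusted over the list alone. Nid1 differed by 0.57 ± 0.123 (SE, adjusted p = 0.116), Serpinh1 by 0.55 ± 0.136 (SE, adjusted p = 0.193), Col1a1 by 1.07 ± 0.312 (SE, adjusted p = 0.299) and Col3a1 by 0.60 ± 0.211 (SE, adjusted p = 0.455). Hsd11b1 differed by 1.16 ± 0.229 (SE, adjusted p = 0.114) and Pdgfa by -0.68 ± 0.129 (SE, adjusted p = 0.114), neither past the threshold. For Hsd11b1 the SS pairs at 3 days were not alike, at 0.40, 0.39 and -0.62.

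Proximal tubule markers differed by 0.477 at 3 days, 8 of 9 positive (list adjusted p = 0.0212; adjusted p = 0.514 with an estimated correlation). Anpep differed by 1.01 ± 0.454 and Kap by 0.86 ± 0.334. Thick ascending limb and distal tubule markers differed by -0.17, 6 of 6 negative (list adjusted p = 0.0355; adjusted p = 0.376 with an estimated correlation). Ppp1r1a differed by -0.32 ± 0.113, Egf by -0.26 ± 0.117 and uromodulin (Umod) by -0.15 ± 0.159. Glycolysis and gluconeogenesis genes differed by -0.113, 7 of 9 negative (list adjusted p = 0.0339; adjusted p = 0.324 with an estimated correlation). The lactate dehydrogenase Ldhb differed by -0.32 ± 0.111, the aldolase Aldoa by -0.26 ± 0.0917 and the hexokinase Hk1 by -0.18 ± 0.0924. In these 3 lists 0 genes passed, also when adjusted over the list alone.

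Of 824 probes 0 passed for the strain difference at 3 days in limma, with 69 at an unadjusted p under 0.05 where 41.2 would by chance. The remaining genes named were Tubb5 at 0.50 ± 0.115 and Acsl3 at -0.57 ± 0.131 (both adjusted p = 0.137), and Gnrhr at -0.65 ± 0.139 (adjusted p = 0.116). They also included the microtubule regulator Stmn1 at 0.71 ± 0.197 and the proteoglycan Sdc4 at -0.29 ± 0.0801 (both adjusted p = 0.282) and Gcgr at -0.51 ± 0.154 (adjusted p = 0.328). An array-level fit gave 7 probes, arrays scaled to one spread 7, quantile normalization 5 and the use of single dye orientations 1. Lists numbered 4 of 17 past the threshold, but 0 without pair 2 of SS-13BN/Mcw at 3 days.

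Over both times together, which asks for genes that differed between the strains at either time, 0 of 822 probes passed the limma F test, 54 had an unadjusted p under 0.05 where 41.1 would by chance, and an array-level fit gave 12. Pdgfa, Hsd11b1 and Nid1 (each adjusted p = 0.256) and Gnrhr and the prolyl peptidase Prep (both adjusted p = 0.291) had the smallest p among named genes. Prep stood at 0.017 and -0.082 in SS and at -0.55 and -0.67 in SS-13BN/Mcw, overnight and at 3 days. The study combined its arrays with those of an earlier study to ask about patterns in time, and the latter were not analysed here.

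**Figure D3:**
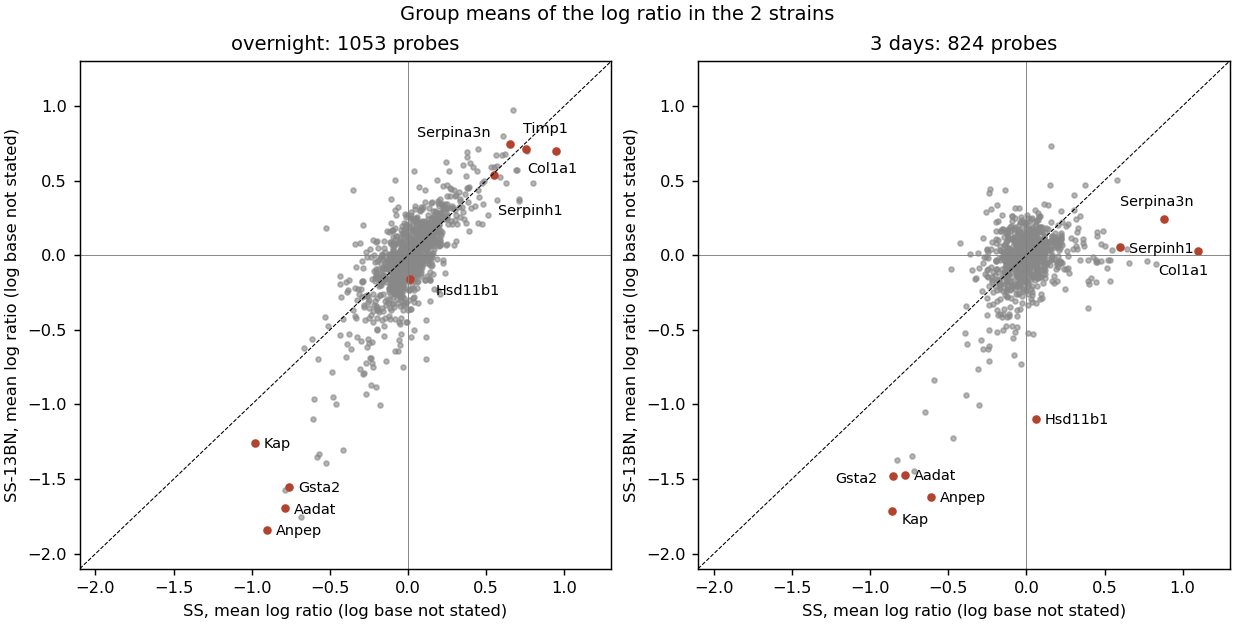
Mean log ratio (base not stated) of each probe in SS (horizontal) and SS-13BN/Mcw (vertical), overnight (1053 probes) and at 3 days (824 probes), with the line of equal values and named genes in red. Across probes r was 0.771 overnight and 0.461 at 3 days, where Col1a1 and Serpinh1 lay near 0 in SS-13BN/Mcw.

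Between the strains the mean log ratios correlated across probes with Pearson r = 0.771 and Spearman rho = 0.712 overnight, and with r = 0.461 and rho = 0.302 at 3 days, probes not being independent replicates. Overnight 8 positive probes passed in both strains, where 0.366 would by independence, 1 negative did (0.0731 by independence), and 0 had opposite signs. Both strains took the spread of a probe from the same fit, so calls are linked even without a like response. The numbers by independence are therefore likely too low. Of the 112 probes past the threshold in SS-13BN/Mcw overnight that were measured in both strains, 108 had the same sign in SS, and at 3 days 20 of 26 did. Within SS, overnight and 3 days correlated with r = 0.782 (rho = 0.681), and within SS-13BN/Mcw with r = 0.688 (rho = 0.47). Low-numbered rats taken as shared by both times gave r = 0.505 and 0.504 in simulations with no response. That r is set by the simulation, which gave both rats of a pair the same spread. It therefore cannot be weighed against the observed r. The covariance was 0.0296 in SS, against 0.00792 simulated, and 0.0501 in SS-13BN/Mcw, against 0.00795 simulated. Without pair 1 of SS at 3 days the strain correlation at 3 days was 0.251 and the time correlation within SS 0.487.

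The time comparisons ask what differed between 3 days and overnight, as 3 days minus overnight. In SS-13BN/Mcw the matrix genes were lower in the ratio at 3 days by -0.315 on average, 15 of 17 negative, with 0 past the threshold and 2 when adjusted over the list alone (list adjusted p = 0.000319; adjusted p = 0.451 with an estimated correlation). Timp1 differed by -0.55 ± 0.134 (SE, adjusted p = 0.276) and Serpinh1 by -0.48 ± 0.137 (SE, adjusted p = 0.282). The proteoglycan decorin (Dcn) differed by -0.81 ± 0.351 (SE, adjusted p = 0.424) and Nid1 by -0.27 ± 0.124 (SE, adjusted p = 0.431). Hpd differed by 0.62 ± 0.131 and Hsd11b1 by -0.94 ± 0.23 (SE, both adjusted p = 0.276), while Hsd11b2, which inactivates glucocorticoid in the collecting duct, differed by 0.50 ± 0.131 (SE, adjusted p = 0.276).

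Thick ascending limb and distal tubule markers were higher in the ratio at 3 days in SS-13BN/Mcw by 0.226, 6 of 6 positive (list adjusted p = 0.0433; adjusted p = 0.451 with an estimated correlation). The creatine kinase Ckb differed by 0.37 ± 0.162, Slc12a1 by 0.23 ± 0.113 and Umod by 0.29 ± 0.16. Oxidative phosphorylation and citrate cycle genes differed by 0.076, 20 of 24 positive (list adjusted p = 0.0433; adjusted p = 0.533 with an estimated correlation). Idh3g, of the citrate cycle, differed by 0.31 ± 0.122, the respiratory chain subunit Cox8a by 0.27 ± 0.111 and the ATP synthase subunit Atp5f1c by 0.22 ± 0.111, with the subunit Atp5f1d apart at -1.02 ± 0.454. Ribosomal protein genes differed by -0.0858, 23 of 28 negative (list adjusted p = 0.0476; adjusted p = 0.653 with an estimated correlation). Eif5 differed by -0.25 ± 0.123, Rps6 by -0.23 ± 0.117, Rpl30 by -0.21 ± 0.15 and Rps7 by -0.15 ± 0.098. In these 3 lists 0 genes passed, also when adjusted over the list alone.

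In SS-13BN/Mcw 0 of 897 probes passed between the times in limma and 101 had an unadjusted p under 0.05 where 44.85 would by chance. Other genes with the smallest p were Scnn1a at 0.37 ± 0.0861, Gcgr at 0.62 ± 0.155, Pdgfa at 0.49 ± 0.13, Clu at -0.59 ± 0.153 and Tubb5 at -0.43 ± 0.116 (each adjusted p = 0.276). With the low-numbered rat as a fixed block, 10 probes passed, 1 positive and 9 negative, among them Hpd (adjusted p = 0.0252), Hsd11b1 (adjusted p = 0.0252) and Clu (adjusted p = 0.0477). With that block 1 list passed in place of 4, the matrix genes (list adjusted p = 9.43e-06; adjusted p = 0.598 with an estimated correlation). An array-level fit gave 8 probes.

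In SS rats 0 of 880 probes passed between the times in limma, 17 had an unadjusted p under 0.05 where 44 would by chance, and an array-level fit gave 0. Both fits leave out the likely link between pairs of the same low-numbered rat. With that rat as a block 0 probes passed and 34 had an unadjusted p under 0.05. In the main fit the genes with the smallest p had an adjusted p of 0.988. They were Akt1 at 0.75 ± 0.147, Foxq1 at 0.60 ± 0.196, the signalling genes Gng7 at 0.27 ± 0.0987 and Grb2 at 0.31 ± 0.116, and Stmn1 at 0.46 ± 0.198 on the positive side. On the negative side were the cholesterol synthesis genes Msmo1 at -0.53 ± 0.165 and Mvd at -0.48 ± 0.153, Sdc4 at -0.23 ± 0.0807, Vcam1 at -0.49 ± 0.166 and Tsc22d1 at -0.48 ± 0.175. Of 18 lists 0 passed, and with the low-numbered rat as a block 1 did, inflammation and adhesion genes with a mean of -0.185 (list adjusted p = 0.0144).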

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

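Tests chosen only after the result was seen are the comparison of thick ascending limb markers with other cell types in each group, both tests of the matrix difference, by the proximal tubule score and by the removal of single pairs, and both tests of Hsd11b1. For the matrix difference an earlier bound, a difference under 2 standard errors without 1 of the 6 pairs, was met, but it was met for 5 of the 6 pairs and so named no single pair. For Hsd11b1 an earlier bound on single arrays, that the highest array lie below 0.5 times the group mean, was missed (-0.499 against -0.548), and the test given here uses pair means.

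Proximal tubule markers lay on the negative side in 12 of 12 pairs, with group means of -0.526 in SS overnight, -0.463 in SS at 3 days, -1.1 in SS-13BN/Mcw overnight and -0.945 in SS-13BN/Mcw at 3 days. A dye bias would turn with the dyes, but the mean score was -0.69 (SE 0.111) in the orientation nearer to 0 and -0.831 (SE 0.13) in the other. Ratios left unturned would put the link between pairs with the same low rat number into the differences between swapped arrays, but it lay in their means, by 0.451 (SE 0.124) more and in 6 of 6 rats. Deviations of the 3 pairs of a group sum to 0, so the rats of a strain are not independent and this SE is rough. A lower share of proximal tubule alone would raise all other cell types alike. Thick ascending limb markers instead lay below those of other cell types overnight, by -0.281 (SE 0.0766) in SS and -0.364 (SE 0.0825) in SS-13BN/Mcw. Each SE rests on 3 pairs and is itself imprecise, so the overnight values weigh against such a share but do not exclude it. In SS at 3 days, at -0.269 (SE 0.138), and in SS-13BN/Mcw at 3 days, at -0.0342 (SE 0.0574) with thick ascending limb markers near 0 (0.00179), the 3 pairs leave such a share open. An effect of salt on tubule gene expression may underlie the pattern, but so could the part of the kidney that was sampled, and neither was tested; the unstated numerator also leaves open which rat had less.

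Extracellular matrix genes differed between the strains at 3 days by 0.295, by 0.293 (SE 0.14) in pair scores. A lower share of proximal tubule in the ratio would raise matrix genes, so a difference in share between the strains would need a lower proximal tubule score in SS. The score was higher in SS by 0.482 (SE 0.271), within 2 standard errors of 0, so such a difference stays open. An earlier test that put the score of each pair into the fit (0.476, SE 0.121) was dropped, since a share effect would itself enlarge the adjusted difference. A single rat pair could not be excluded as the source, since without pair 1 of SS at 3 days the difference was 0.168 (SE 0.13). Without 4 of the other pairs it was 0.302, 0.278, 0.278 and 0.324 (SE 0.165 to 0.167), near the full value though within 2 standard errors of 0, and without pair 3 of SS it was 0.41 (SE 0.135). The removals other than that of pair 1 of SS thus name no pair as the source. The strain itself, slide order and the small number of pairs stay open, as untested explanations.

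Hsd11b1 stood at -1.10 in SS-13BN/Mcw at 3 days, with pairs at -1.2, -1.15 and -0.936. A single rat pair would leave the others near 0, but the pair with the 2nd lowest value was at -1.15 (SD between pairs 0.327). A lower share of proximal tubule alone would have given -1.27 overnight, in step with the marker score, but the value there was -0.161, higher by 1.11 (SE 0.162). That SE is of the overnight value alone. It leaves out the error of the -1.27, which rests on the 3-day values and on marker scores with an SD of 0.48 overnight. The distance from such a share in standard errors is therefore overstated. A change of this gene within the tubule between the times is a candidate explanation, found and tested on the same data. Over all genes the time difference did not pass (adjusted p = 0.276), but it did with the low-numbered rat as a block (0.0252) and in the array-level fit (0.0297), with a range over alternatives up to 0.791 with arrays turned by dye, where the difference was 0.18. The strain difference at 3 days did not pass (0.114), but it did with arrays scaled (0.0403), in the array-level fit (0.00271) and without pair 3 of SS at 3 days (0.000222), with a range up to 0.852 with arrays turned by dye, where it was -0.20. Pair 3 of SS at 3 days stood at -0.62, on the side of SS-13BN/Mcw, and pairs 1 and 2 at 0.40 and 0.39.

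The array of pair 3 of SS-13BN/Mcw at 3 days with the high-numbered rat in Cy5 had an SD of 0.4427 over its probes, the next highest in its group being 0.354. It stood out from the 6 arrays of its group in 1 of 12 such tests, of which chance gives about 1 in 20.

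Beside the matrix genes, list tests of the difference itself passed as follows. Overnight the strain difference was 0.201 for antioxidant and oxidant enzymes and 0.44 for proximal tubule markers. At 3 days it was -0.113 for glycolysis and gluconeogenesis, 0.477 for proximal tubule markers and -0.17 for thick ascending limb and distal tubule markers. In SS-13BN/Mcw the difference between 3 days and overnight was -0.315 for extracellular matrix, 0.076 for oxidative phosphorylation, -0.0858 for ribosomal proteins and 0.226 for thick ascending limb and distal tubule markers. None of these passed with an estimated correlation.

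For some named genes all pairs of one group had the opposite sign to all pairs of the other, while the limma test of the difference did not pass. For the strain difference overnight they were Cycs at 0.66, Myl2 at 0.46 and Sfrp4 at -0.39. At 3 days they were Nid1 at 0.57, Tubb5 at 0.50, Pdgfa at -0.68, Sdc4 at -0.29 and Ldhb at -0.32. Between the times in SS they were Foxq1 at 0.60, Gng7 at 0.27, Grb2 at 0.31 and Sdc4 at -0.23. In SS-13BN/Mcw they were Scnn1a at 0.37, Hsd11b2 at 0.50, Tubb5 at -0.43, Dcn at -0.81, Atp5f1d at -1.02 and Rps7 at -0.15.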

How the results depend on the processing

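Turning arrays by dye, and leaving out pairs in the correlations, were chosen after seeing the data; all other alternatives were planned. Counts are of probes past the threshold, and the cause of a shift was not tested unless stated. With arrays scaled to one median absolute deviation the counts were 51 for SS overnight (main value 13), 9 for SS at 3 days (3), 61 for SS-13BN/Mcw at 3 days (27) and 7 for the strain difference at 3 days (0). After quantile normalization they were 65, 16, 64 and 5. In the array-level fit with a dye term, which counts both arrays of a pair, they were 49 for SS overnight, 38 for SS at 3 days, 226 for SS-13BN/Mcw overnight (116), 58 for SS-13BN/Mcw at 3 days, 1 and 7 for the strain differences overnight and at 3 days (0 each), 8 for the time difference in SS-13BN/Mcw (0) and 12 for the F test (0). Fits of the groups compared alone, with fewer degrees of freedom, gave 31 for SS overnight, 0 for SS at 3 days and 0 for SS-13BN/Mcw overnight. They were not run for the common response and the F test, which use all groups. Requiring all 3 pairs gave 1 for SS at 3 days, and single dye orientations gave 1 for the strain difference at 3 days. The low-numbered rat as a block gave 5 for SS at 3 days, 10 for the time difference in SS-13BN/Mcw and 176 for the common response. By its construction the threshold of 0.1 gave more, 33 for SS overnight, 8 for SS at 3 days and 207 for SS-13BN/Mcw overnight. Arrays turned by dye gave 325, 344, 309 and 299 for SS overnight, SS at 3 days, SS-13BN/Mcw overnight and SS-13BN/Mcw at 3 days, and 568 for the common response (234), since turning puts the dye effect into the mean of a pair.

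For gene lists, camera with an estimated correlation gave 0 in all 8 comparisons with a list past the threshold (SS overnight 6, SS at 3 days 3, SS-13BN/Mcw overnight 3 and at 3 days 1, strain differences 2 and 4, time difference in SS-13BN/Mcw 4, common response 4). It was run on fewer genes. Fry gave 0 for SS overnight, 0 for SS at 3 days, 5 for SS-13BN/Mcw at 3 days, 0 and 2 for the strain differences and 1 for the time difference in SS-13BN/Mcw. The lists it called were in part others than those past the main test. Proximal tubule markers passed by fry in SS-13BN/Mcw overnight (fry adjusted p = 0.00996), at 3 days (0.0184) and in the common response (0.00137). In SS they did not, at 0.21 overnight and 0.188 at 3 days. In the common response matrix genes (0.0118) and thick ascending limb and distal tubule markers (0.00137) also passed. Ribosomal protein genes there did not (0.0714). For the time difference in SS-13BN/Mcw fry called sodium, potassium and chloride transport (fry adjusted p = 0.00587), with matrix genes at 0.148. For the strain difference at 3 days it called the same list (0.0304) and glycolysis and gluconeogenesis (0.0265), with matrix genes at 0.197. Scaling gave 2 lists for the strain difference at 3 days, 1 for the time difference in SS and 2 for the common response, and the block gave 1 for each time difference. Tested list by list with the estimated correlation, fry, values as deposited, scaling and the block, 78 results stayed past the threshold and 53 did not. Of these fry gave 6 and 19.

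Each pair was also left out in turn. Counts then ranged from 0 (without pair 1, and without pair 3) to 6 (without pair 2) in SS overnight. In SS at 3 days they ranged from 0 (without pair 1, and without pair 2) to 10 (without pair 3). In SS-13BN/Mcw overnight the range was 12 (without pair 3) to 92 (without pair 1), with 45 without pair 2. In SS-13BN/Mcw at 3 days it was 0 (without pair 2, and without pair 3) to 29 (without pair 1). Strain differences stayed at 0 overnight and ranged from 0 to 1 at 3 days (1 without pair 3 of SS, and without pair 2 of SS-13BN/Mcw, at that time). The F test ranged from 0 to 1 (1 without pair 3 of SS at 3 days). Both time differences stayed at 0, and the common response ranged from 167 to 269. Lists ranged from 5 to 6 in SS overnight, 2 to 3 in SS at 3 days, 2 to 4 and 1 to 1 in SS-13BN/Mcw overnight and at 3 days, and 2 to 4 for the common response (2 without pair 1 of SS at 3 days, of SS-13BN/Mcw overnight, or of SS-13BN/Mcw at 3 days). For the strain differences they ranged from 0 (without pair 3 of SS-13BN/Mcw) to 4 overnight and from 0 (without pair 2 of SS-13BN/Mcw) to 5 at 3 days. For the time differences the ranges were 0 to 1 in SS and 1 (without pair 2 or pair 3 of SS-13BN/Mcw at 3 days) to 4 in SS-13BN/Mcw. Correlations ranged from 0.658 to 0.767 and from 0.251 (without pair 1 of SS at 3 days) to 0.528 between the strains overnight and at 3 days. Within SS the range was 0.487 (without the same pair) to 0.798 and within SS-13BN/Mcw 0.555 to 0.711, where Spearman's rho was 0.47 beside r = 0.688. A group left with fewer pairs takes its spread from the other groups as well.

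Of named genes past the threshold, 707 results stayed past it under alternatives other than leaving out a pair or turning arrays by dye, and 43 did not. Of those not past it, 1225 stayed so and 113 passed. With a pair left out 325 of the former stayed past it and 83 did not, and 8 of the latter passed while 628 did not. Of the 707, 71 came from the threshold of 0.1, under which no call can be lost, and 71 from values as deposited. Of the 43, 29 came from the fit of the groups compared alone, in which 19 stayed past the threshold. The 1 value reversed by leaving out a pair was Ckb in SS at 3 days, 0.022 without pair 1 of that group, -0.24 without pair 3 and -0.10 with all pairs. What signal over background limits could not be asked, since the table holds ratios alone.

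With arrays turned by dye, of named genes past the threshold 22 results stayed past it, 28 did not and 21 reversed. Of those not past it 61 stayed so, 8 passed and 54 reversed. Reversed values were, for SS overnight Timp1 -0.0214, Akt1 0.0201, Ephx1 0.0583, Kap 0.0177, Foxq1 0.173, Ptger1 0.0751, C1qb -0.232, Rps6 -0.0237, Ppp1r1a 0.0658, Egf 0.0203; for SS at 3 days Tubb5 -0.440, Calr -0.117, Pard3 0.177, Ephx1 0.00802, Pcsk6 0.0281, Gcgr 0.149, Ppp1r1a 0.0780, Kap 0.228, Cyp2c23 0.0707, Hao2 0.137; for SS-13BN/Mcw overnight Serpina3n -0.0181, Timp1 -0.196, Hao2 0.0454, Agxt2 0.0263, Ggt1 0.317, Lrp2 0.213, Col1a1 -0.0177, Eif5 -0.176; for SS-13BN/Mcw at 3 days Acsl3 -0.0489, Gnrhr -0.216, Rbck1 -0.251, Kap 0.0858, Hao2 0.140, Akr7a3 0.0769, Hsd11b1 0.257, Dpp4 0.0484; for the strain difference overnight Cycs -0.0930, Myl2 -0.0548, Acads -0.0226, Slc15a2 -0.144, Foxq1 0.0993, Sfrp4 0.178, Gng7 0.00646, Ppp1r15a 0.256, Gsta2 -0.148; for that at 3 days Hsd11b1 -0.202, Nid1 -0.0123, Tubb5 -0.0258, Stmn1 -0.0447, Gnrhr 0.194, Acsl3 0.202, Gcgr 0.0522, Ldhb 0.00313, Hao2 -0.00300, Slc12a1 0.0289, Umod 0.108; for the time difference in SS Akt1 -0.0789, Foxq1 -0.248, Grb2 -0.138, Stmn1 -0.0794, Mvd 0.272; for that in SS-13BN/Mcw Scnn1a -0.0276, Hsd11b1 0.182, Clu 0.128, Dcn 0.0462, Nid1 0.0125, Atp5f1c -0.0509, Eif5 0.0601, Rps7 0.0576, Ppp1r1a -0.0564, Umod -0.0659; for the common response Serpina3n -0.00447, Kap 0.121, Hao2 0.0508, Ppp1r1a 0.0899. Of lists past the threshold 1 stayed past it, 21 did not and 5 turned to the other side of the other genes: arachidonic acid metabolism (0.0559) and thick ascending limb markers (0.0102) in SS overnight, proximal tubule markers in the strain difference overnight (-0.0668), thick ascending limb markers in that at 3 days (-0.0156) and oxidative phosphorylation in the time difference in SS-13BN/Mcw (-0.00185). Counts of lists were 1 for SS overnight, 1 for SS at 3 days, 2 for SS-13BN/Mcw at 3 days, 0 for each strain difference and for the time difference in SS-13BN/Mcw, and 1 for the common response. Correlations between the strains at 3 days and between the times in SS-13BN/Mcw were 0.86 and 0.834.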

Other observations

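The genes in this part were chosen after their values were seen, while the fits, lists and splits they come from were planned, except the restriction to splits that part the pairs of each rat. Antioxidant and oxidant enzymes went both ways in the common response, with 2 of 16 positive and 7 negative past the threshold, and the list did not pass (adjusted p = 0.42). Gsta2 at -1.16 and the glutathione transferases Gstm2 at -0.48 and Gstm1 at -0.23 were negative, as were the peroxidases Gpx4 at -0.20 and Prdx6 at -0.34, glutathione synthetase (Gss) at -0.26 and the superoxide dismutase Sod1 at -0.23. Mt2A at 0.39 and Xdh, which encodes xanthine dehydrogenase, at 0.33 were positive. Genes of fatty acid and lipid metabolism had 2 positive and 8 negative of 28 past the threshold (list adjusted p = 0.728). The negative ones included the mitochondrial oxidation genes Etfa and Acads, both at -0.31, and the positive ones were Sqle, of cholesterol synthesis, at 0.25 and the apolipoprotein Apoe at 0.44.

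Ion transport genes had Atp1b1 at 0.28 and Slc12a2 at 0.15 positive and Slc12a1 at -0.24 negative (list adjusted p = 0.766). By fry this list passed in the common response (adjusted p = 0.017) and in SS-13BN/Mcw at 3 days (adjusted p = 0.00231). In the common response water and urea handling (adjusted p = 0.974), immediate early genes (0.766), heat shock proteins (0.618), oxidative phosphorylation (0.728), glycolysis (0.766), growth factors (0.794), collecting duct (0.766), endothelial and vascular smooth muscle (0.532) and blood and immune cell markers (0.761) did not pass, and 1 further list is not described here.

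With the low-numbered rat as a block, the time difference in SS-13BN/Mcw held 10 probes, of which 1 had no gene name. Beside Hpd, Hsd11b1 and Clu they were the matrix protein gene Mgp at -0.63, Spink1l at -0.55, the fatty acid binding protein Fabp4 at -0.66, the smooth muscle gene Tagln at -0.76, the complement gene C1s at -1.01 and Ctxn1 at -0.80. They were 0 without the block.

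Other splits of the samples were counted for each comparison. For a single group, flipping the sign of pairs gives 4 splits, too few for a share under 0.05, and only the real one gave as many probes (1 of 4 in each). The real count was 13 and the highest other 0 in SS overnight, 3 and 0 in SS at 3 days, 116 and 0 in SS-13BN/Mcw overnight, and 27 and 0 in SS-13BN/Mcw at 3 days. For a difference there are 10 splits, again too few. All 10 gave as many as the real count of 0, and the highest other was 0 for the strain differences overnight and at 3 days, 0 for the time difference in SS-13BN/Mcw and 14 for that in SS. The 14 came from exchanging pair 3 overnight with pair 1 at 3 days, which points to a structure of the SS pairs beyond the time. That split puts both pairs of rat 1 on one side and both pairs of rat 3 on the other, and the cause was not tested. Among the 4 splits that part the pairs of each low-numbered rat, as the real one does, the highest other was 0 in both strains. For the F test 100 of 100 splits gave at least the real 0, with a highest other of 0. Any split reaches a real count of 0, so these shares carry no information for the differences and the F test. For the common response 2 of 32 gave at least the real 234, the other being 249 with the sign of rat 3 of SS flipped, so chance is not excluded.

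Lists were counted in the same splits. In groups 1 of 4 reached the real 6 in SS overnight (highest other 4), 2 of 4 the real 3 in SS at 3 days (3), 4 of 4 the real 3 in SS-13BN/Mcw overnight (4) and 4 of 4 the real 1 in SS-13BN/Mcw at 3 days (1). In differences 9 of 10 reached the real 2 of the strain difference overnight (6), 1 of 10 the real 4 at 3 days (2), 10 of 10 the real 0 of the time difference in SS (3) and 2 of 10 the real 4 of that in SS-13BN/Mcw (6). Among the 4 splits that part the pairs of each low-numbered rat the highest other was 1 list for each time difference. All these splits are too few for a share under 0.05, and a real 0 is reached by any split. For the common response 7 of 32 reached the real 4 (highest other 5), and chance is not excluded.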
